A study of Mus musculus with 8 samples.

How the data were processed

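Single-cell RNA sequencing libraries of CD45-sorted brain cells were analysed from C57BL/6 and RAG1-KO mice injected with EO771 cells, at D4 and D10. Per the labels, brains were dissociated with Collagenase D, cells were tagged per mouse with CellPlex oligonucleotides, and libraries were made with a 10x 3′ kit and sequenced on a NovaSeq. The deposited matrices hold raw UMI counts per gene and cell for each gene of the annotation and 12 tags, made by the authors with Cell Ranger 6.1.2 per the file headers, while the submitters' notes name Cell Ranger 3.0.2 and the builds GRCh38 and mm10. Nothing in the values decides between these versions. How barcodes were called as cells and how tags were assigned to mice is not given in the sources used here.

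Each of the 12 file sets belongs to 1 labelled replicate. The sets of RAG1-KO D4 replicates 1 and 2 were identical byte for byte and were counted as 1 mouse, which left 11 mice. Mice of the same group shared 0 cell barcodes over 10 pairs, where 14.8 would be expected at the rate of pairs from different groups, which shared 74 over 45 pairs. This pattern is that of 1 droplet capture per group, so capture and group cannot be separated. C57BL/6 D10 replicate 2 had 255 barcodes, of which 245 were kept. Of its 810181 tag UMIs, 730555 were of its own tag and 26582 and 53025 of the tags of the other 2 mice of its group, so some of its barcodes may be of those mice. Total UMIs per mouse ranged from 2253275 to 70706464.

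Cells with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept. Doublets were scored per group with Scrublet in scanpy 1.11.5 at an expected rate of 0.06, and cells scoring above 0.25 were removed. That threshold was set after the scores were seen, because the automatic threshold called 133, 3, 58 and 4 cells in C57BL/6 D10, C57BL/6 D4, RAG1-KO D10 and RAG1-KO D4. At 0.25, 223 of 8799, 102 of 8847, 76 of 6396 and 87 of 3869 cells were called. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes gave 30 principal components, 15 neighbours and Leiden clusters at resolution 1 (leidenalg 0.10.2, seed 0). No integration across groups was made. Clusters were named from 187 markers fixed before the data were examined, as were the comparisons, gene lists and tests. A name needed at least 3 markers of a type present in 25% of cells. Rules for border-associated macrophages (5 of 10 top genes), cycling cells (4) and stress (3) were set after seeing the clusters. Names end in "-like" because they rest on transcripts alone.

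UMIs were summed per mouse and class with at least 20 cells. Differential expression was tested with edgeR 4.0.16 (TMM scaling, its default filter on low counts, quasi-likelihood F test, 1 model of 4 groups per class), in R 4.3.3, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM of a single gene in a class are UMIs per 1e6 UMIs of the class in a mouse, with the totals scaled by TMM. Summed CPM of several genes, and CPM of single cells or within clusters, carry no TMM scaling. Gene lists, 25 in all, were tested against the other genes with camera in limma 3.58.1, at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison; members were also adjusted over the list alone. Of 287 list tests, 165 were called with the preset correlation and 7 of these with the estimated one. Cell shares were compared with exact permutation tests of mice within time points or genotypes, two-sided, with SciPy 1.17.1.

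Genes named in the text had an absolute log2 fold change of at least 1, a mean log2 CPM of at least 4 and groups that did not overlap (not required for the interaction), up to 12 per direction, with up to 4 members of each list by smallest adjusted p; not every gene the rule admits is given. Predicted genes, ribosomal, mitochondrial, haemoglobin and antigen receptor genes were left out except as list members. Coordinates are from GENCODE vM21 on mm10. Intervals and limits for counts of 0 (3 counts) cover counting error only.

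On simulated data with 200 changed genes, the percentage of 2-fold and 4-fold changes recovered was 74 and 96 for microglia-like cells between genotypes at D10, 81 and 98 for monocyte/macrophage-like cells, and 20 and 77 for neutrophil-like cells. The raised list was called in all 12 simulated comparisons and no unchanged list was. Each gene was drawn independently there, so this does not test lists whose genes move together. Alternatives were DESeq2 1.42.0, its size factors, no filter on low counts, only the compared groups, 50 cells per mouse, 100 cells per mouse, stricter cell filters (1000 genes, 5% mitochondrial), doublets kept, resolution 2, the identical file set counted as a mouse, each mouse left out, and other denominators and a log scale for shares. Leaving out cycling, stress-led, immature neutrophil or border-associated clusters was chosen after seeing the data. The classes named border-associated macrophage, endothelial, innate lymphoid, tumour-like and unnamed had too few cells for tests of expression. Tag counts were not used here beyond checks of sample identity.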

Results

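Messenger RNA of single leukocytes was sequenced from the brains of mice injected intracranially with EO771 cells, a mouse breast cancer line that carried GFP and luciferase. Leukocytes were selected by high or intermediate CD45, a surface protein that microglia carry at a lower level than blood-derived leukocytes. C57BL/6 mice were compared with RAG1-KO mice, which lack the recombinase needed to make T and B cells, at D4 and at D10. The labels do not say from which day these are counted. The replicates were separate mice, each with its own oligonucleotide tag. There were 3 C57BL/6 mice at D4, 3 at D10, 2 RAG1-KO mice at D4 and 3 at D10. The RAG1-KO D4 mice are replicates 1 and 3, since the file set of replicate 2 was identical byte for byte to that of replicate 1 and was counted once.

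After filtering, 27423 cells remained, of which 12383 were microglia-like, 7430 monocyte/macrophage-like, 2199 dendritic-like, 2052 T-like, 1543 NK-like, 795 neutrophil-like and 353 B-like. Total UMI counts in C57BL/6 D4 replicates 1 to 3 were 18311228, 25873328 and 10673126. In C57BL/6 D10 replicates 1 to 3 they were 35860888, 2253275 and 70706464. RAG1-KO D4 replicates 1 and 3 had 4043192 and 23441094 UMIs. RAG1-KO D10 replicates 1 to 3 had 12466453, 44291312 and 17376020. Median UMIs per cell barcode ranged from 5134 in C57BL/6 D4 replicate 3 to 11409 in RAG1-KO D10 replicate 3. The C57BL/6 D10 mice differed in size by far the most, since replicate 2 contributed 255 barcodes and replicates 1 and 3 contributed 3104 and 5552.

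Transcripts of the deleted gene were rare in every mouse. Rag1 (mm10 chromosome 2, 101638282 to 101649501) had 8, 8 and 15 UMIs in C57BL/6 D4 mice, 0, 0 and 1 in C57BL/6 D10 mice, 4 and 41 in RAG1-KO D4 mice, and 3, 16 and 7 in RAG1-KO D10 mice. A 3′ tag need not lie in the deleted part of the gene, so these counts test nothing about the genotype. The neighbouring Rag2 (101624718 to 101632529) had 3, 2 and 1 UMIs in the C57BL/6 D4 mice and 6 in RAG1-KO D4 replicate 3, and none in the other 7 mice. Xist was present in all 11 mice, and of 4 Y-linked genes Ddx3y and Eif2s3y had 0 UMIs, Kdm5d had 1 to 5 in 9 mice and 0 in 2, and Uty had 1 UMI in 2 mice.

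T-like and B-like cells, the lineages that need RAG1, made up less of the leukocytes in RAG1-KO than in C57BL/6 mice. T-like cells were 7.09% ± 4.04 (SD, n = 3) of all cells in C57BL/6 brains at D4 and 25.6% ± 13.4 (SD, n = 3) at D10. None was found among 10102 RAG1-KO cells, which allows a share of up to 0.0297% with these filters. With doublets kept there were 6 in RAG1-KO D10 replicate 2 and 1 in RAG1-KO D4 replicate 3, and with stricter cell filters 1 in RAG1-KO D10 replicate 1. The genotype difference, averaged over D4 and D10, was −16.4 percentage points for T-like cells (exact two-sided permutation p = 0.01 within time points, Benjamini-Hochberg adjusted p = 0.028 over 14 share tests). B-like cells were 2.88% ± 0.868 of all cells in C57BL/6 mice at D4 and 1.59% ± 0.753 at D10, and differed by −2.09 points (exact two-sided permutation p = 0.005, the smallest that 200 rearrangements allow; adjusted p = 0.018). The 19 B-like cells of RAG1-KO mice all came from D4 replicate 3. They held 766 UMIs of Vpreb1, 349 of Igll1 and 322 of Dntt, genes of B-cell precursors, and 14 of the light-chain constant region Igkc. The 234 B-like cells of C57BL/6 mice at D4 held 159 UMIs of Vpreb1 and 8861 of Igkc. Between D4 and D10 in C57BL/6 mice the T-like share differed by 18.5 points (11.1 without C57BL/6 D10 replicate 2), with an exact two-sided permutation p of 0.1, the smallest that 20 rearrangements of 6 mice allow.

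**Figure D1:**
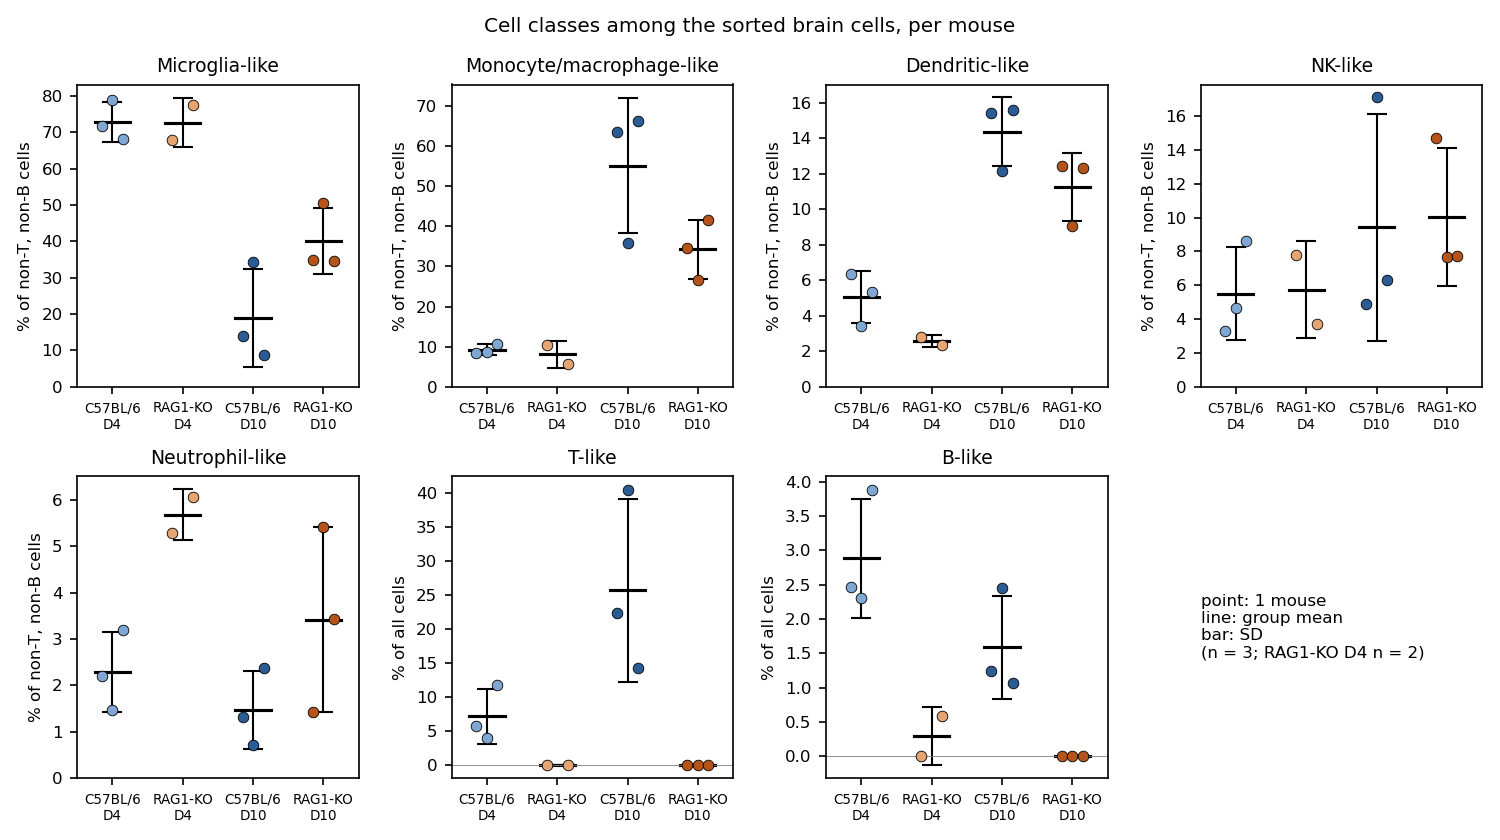
Share of each leukocyte class per mouse (vertical axis, %), by genotype and time point, as points with a line at the group mean and a bar for 1 SD. T-like and B-like shares are of all cells and the others of cells that are neither; T-like cells averaged 25.6% in C57BL/6 and none were found in RAG1-KO brains at D10.

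Among the remaining cells, the microglia-like share fell and monocyte/macrophage-like and dendritic-like shares rose from D4 to D10. Microglia, the resident macrophages of the brain, went from 72.9% ± 5.50 to 19.0% ± 13.5 in C57BL/6 mice and from 72.7% ± 6.77 to 40.1% ± 9.12 in RAG1-KO mice (SD; n as above). C57BL/6 D10 replicates 1 to 3 had 14.1, 34.3 and 8.74%, so their mean rests in large part on replicate 2, with 48 microglia-like cells. The change averaged −43.3 points, while monocytes and macrophages, which enter from the blood, changed by 36.0 points and dendritic cells by 9.01 points (each exact two-sided permutation p = 0.005, adjusted p = 0.018). Monocyte/macrophage-like cells reached 55.1% ± 16.8 in C57BL/6 and 34.2% ± 7.43 in RAG1-KO mice at D10. Neutrophil-like cells took a larger share in RAG1-KO than in C57BL/6 mice, by 2.67 points (exact two-sided permutation p = 0.015, adjusted p = 0.035), with 5.68% ± 0.551 against 2.29% ± 0.866 at D4 and 3.42% ± 2.00 against 1.47% ± 0.845 at D10. The genotype difference did not pass the correction for microglia-like cells (10.4 points, exact two-sided permutation p = 0.15), monocyte/macrophage-like cells (−11.0 points, p = 0.14), dendritic-like cells (−2.79 points, p = 0.03, adjusted p = 0.06) or NK-like cells (0.416 points, p = 0.84). As a share of all cells in place of cells that are neither T- nor B-like, the microglia-like difference was 17.1 points (exact two-sided permutation p = 0.02) and the dendritic-like difference −0.667 points (p = 0.605). No class passed the test of a genotype difference that changed between D4 and D10 (microglia-like 21.3 points, exact permutation p = 0.125).

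At D10, microglia-like cells of RAG1-KO mice had less mRNA of MHC class II, the molecules that present peptides to CD4 T cells, than those of C57BL/6 mice (n = 3 and 3). H2-Eb1, H2-Aa and H2-Ab1, which encode its chains, changed by −4.18 ± 0.61, −3.99 ± 0.58 and −3.28 ± 0.38 (log2 fold change ± SE, RAG1-KO over C57BL/6; edgeR adjusted p = 0.0195, 0.0202 and 0.00665). H2-Aa stood at 389 ± 232 CPM in C57BL/6 and 26.8 ± 8.65 CPM in RAG1-KO mice (mean ± SD). Cd74, the invariant chain that escorts class II molecules, changed by −3.81 ± 0.54 (adjusted p = 0.0171), and Ciita, the transactivator of the class II genes, by −3.24 ± 0.57 (adjusted p = 0.00417). Ciita was near the floor, with 3.11, 2.51 and 4.13 CPM in the C57BL/6 and 0.40, 0.37 and 0.33 CPM in the RAG1-KO D10 replicates. Which cells its few UMIs come from was not tested. Of the 10 MHC class II genes measured, 8 fell over all genes and 8 when adjusted over the list alone, and the set was lower with limma's camera (adjusted p = 8.94e-15, and 0.0176 with an estimated correlation). NK-like cells, which should lack these genes, gave the background. The summed CPM of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 in microglia-like cells was 7.10, 2.69 and 8.33 times that in NK-like cells of the same mouse in the C57BL/6 D10 replicates, and 2.56, 1.30 and 1.14 times in the RAG1-KO D10 replicates. Few cells held much of this, since the top twentieth of microglia-like cells had 51.0, 34.5 and 44.1% of these UMIs in the C57BL/6 D10 replicates. The median microglia-like cell there had 757.5, 555.5 and 707 CPM, and the median NK-like cell 312, 420 and 293. With cells thinned to 2000 UMIs, H2-Aa was found in 24.4, 14.6 and 27.7% of microglia-like and 19.8, 13.04 and 18.3% of NK-like cells, and Cd74 in 55.1, 47.9 and 57.6% against 26.1, 39.1 and 17.9%.

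Targets of interferon gamma, a cytokine made mainly by T and NK cells, fell in the same comparison. The GTPases Iigp1, Gbp2, Gbp4 and Igtp changed by −1.67 ± 0.22, −1.43 ± 0.24, −2.24 ± 0.38 and −0.71 ± 0.11 (edgeR adjusted p = 0.003, 0.015, 0.00843 and 0.00155). Iigp1 averaged 110 ± 23.4 CPM in C57BL/6 and 37.6 ± 8.28 CPM in RAG1-KO mice. Of 28 interferon-gamma induced genes, 10 fell over all genes, and 16 fell and 1 rose when adjusted over the list alone (camera adjusted p = 1.07e-15, and 0.0176 with an estimated correlation). None of the 35 genes induced by type I interferon was called, over all genes or adjusted over the list alone (camera adjusted p = 0.49). Slamf8, Plaat3, S100a6, Lgals3, Itgax and Lst1 completed the 12 largest falls that the naming rule admits, at −1.72 to −1.25, with Lgals3 at 464 ± 161 CPM in C57BL/6 and 176 ± 7.39 CPM in RAG1-KO mice.

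**Figure D2:**
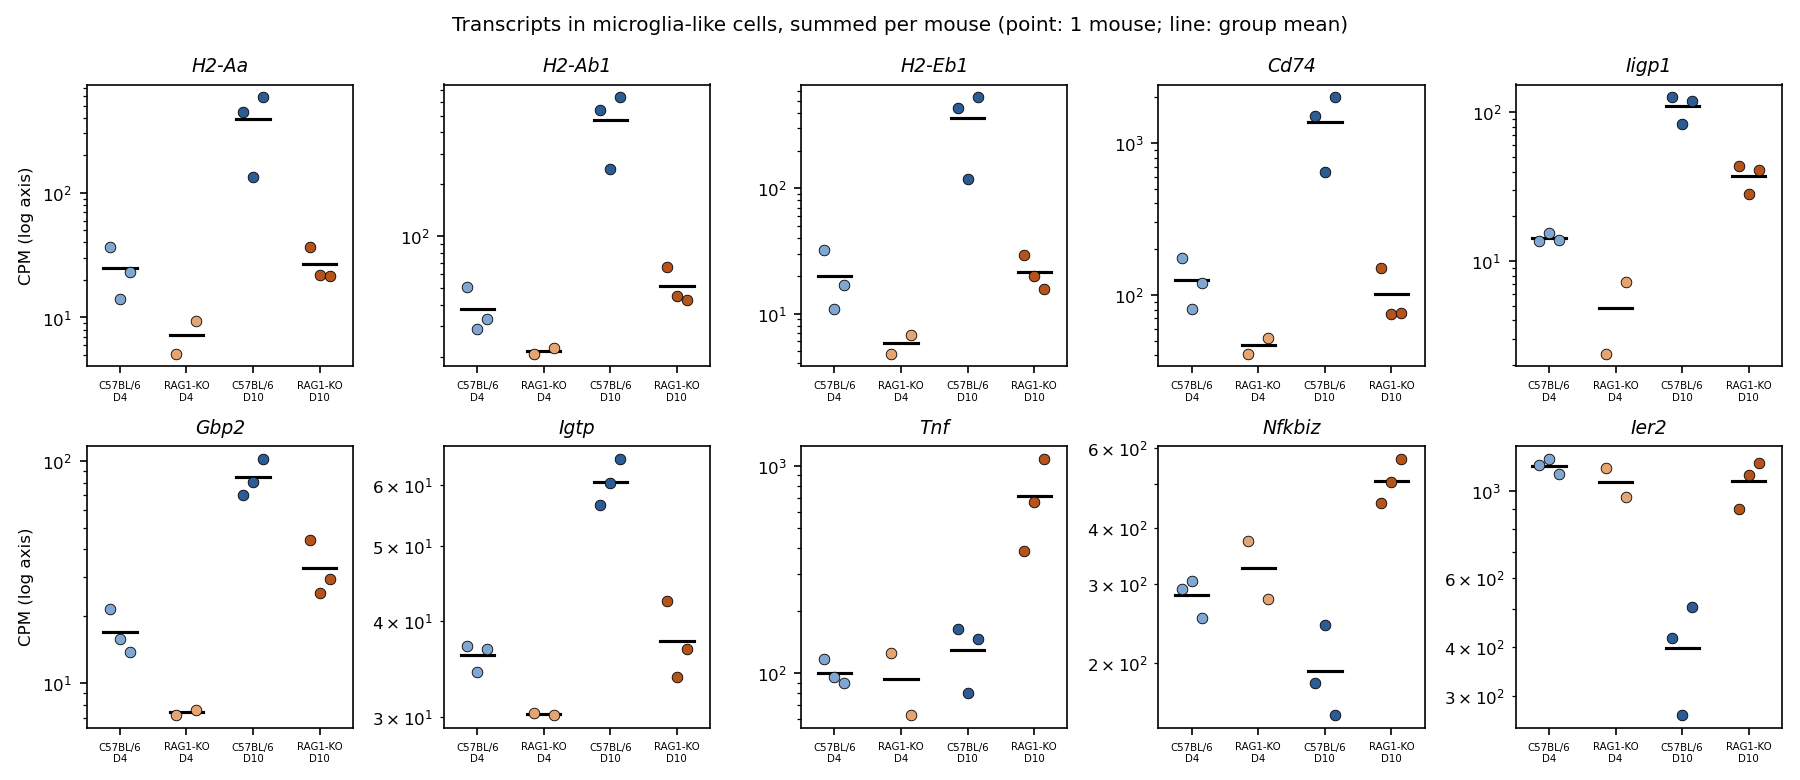
CPM of 10 genes in microglia-like cells summed per mouse (vertical log axis), by genotype and time point; points are mice and lines group means. At D10, H2-Aa averaged 389 CPM in C57BL/6 and 26.8 CPM in RAG1-KO mice, and Tnf 130 and 711 CPM.

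Tnf and 10 of 30 dissociation and immediate early genes, Nfkbiz and Nfkbia among them, were higher in the RAG1-KO microglia at D10. Cluster 3 held 11.5% of the pooled cells in C57BL/6 and 35.2% in RAG1-KO, and cluster 0 held 28.9% and 15.2%, which was not tested. With stricter cell filters, a microglia-like cluster was led by Tnf, Csf1 and Il1a. Tnf and the immediate early genes were not checked within clusters, so a shift between clusters cannot be told apart from a rise within them. Tnf, an inflammatory cytokine, rose by 2.36 ± 0.46 (edgeR adjusted p = 0.0473; 130 ± 43.9 against 711 ± 349 CPM), and Nfkbiz, an NF-kB cofactor, by 1.46 ± 0.16 (adjusted p = 9.03e-05). Ifrd1 rose by 1.43 ± 0.23, Ier2 by 1.37 ± 0.17 and Nfkbia, the NF-kB inhibitor, by 1.21 ± 0.15 (adjusted p = 0.0106, 0.000493 and 0.000114). Of the 30, which enzymatic digestion can also induce, 10 rose over all genes, including Egr1 by 0.91 ± 0.14, and 18 rose and 4 fell when adjusted over the list alone. The set was higher with camera (adjusted p = 5.89e-10), and not with an estimated correlation (adjusted p = 0.147 with an estimated correlation). No call was made for the sets of homeostatic microglial genes (1 of 28 rose, also adjusted over the list alone; camera adjusted p = 0.97) or inflammatory cytokines and chemokines (1 of 28 rose and 2 fell, and 3 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.99). Glycolysis and hypoxia genes were lower as a set (3 of 23 fell and 7 adjusted over the list alone, Ndrg1 by 3.12 ± 0.70 on the log2 scale; camera adjusted p = 1.8e-07, and adjusted p = 0.112 with an estimated correlation).

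In total, 289 of 11627 genes passed an edgeR adjusted p of 0.05 in this comparison, 110 higher and 179 lower in RAG1-KO mice. Lymphocyte transcripts listed as coming from other cells, an origin that was not tested, moved with it. Of 11 such genes 9 fell (10 adjusted over the list alone), and the set was lower (camera adjusted p = 4.49e-19, and 0.00817 with an estimated correlation), with Igkc at −7.37 ± 0.33 and Trbc2 at −4.72 ± 0.40. Brain parenchyma transcripts listed as coming from other cells were lower as a set too, with 0 of 6 called over all genes and 5 adjusted over the list alone (camera adjusted p = 0.000447, and 0.0354 with an estimated correlation). Mitochondrially encoded transcripts fell for 8 of 13 genes (8 adjusted over the list alone), with mt-Co3 at −0.78 ± 0.12 (camera adjusted p = 4.89e-09, and adjusted p = 0.221 with an estimated correlation). Of 42 genes near Rag1 on chromosome 2, where a knockout made in another strain can carry that strain's sequence, 4 were called, against 289 of 11627 over all genes. Adjusted over the list alone, 7 were called (camera adjusted p = 0.35). Camera looks for a shift in a common direction, so it cannot decide on changes that go both ways, as these calls did. Whether calls were more frequent there than elsewhere was not tested. Fnbp4 (90745370 to 90781021) and Tcp11l1 (104657288 to 104712169) rose by 0.49 ± 0.11 and 0.75 ± 0.20, and Cd44 and Nr1h3 fell by 1.49 ± 0.19 and 2.49 ± 0.42 on the log2 scale. The calls for Fnbp4 and Tcp11l1 ended in 7 and 12 of 18 alternatives, and those for Cd44 and Nr1h3 in 0 of 18 and 0 of 13. The number of genes was 98 without C57BL/6 D10 replicate 1, 75 without replicate 3, 792 without RAG1-KO D10 replicate 1, 92 without replicate 2 and 172 without replicate 3, and 127 when the D10 mice were fitted alone. The calls for H2-Aa, H2-Eb1 and Cd74 ended without any 1 of C57BL/6 D10 replicates 1 and 3 and RAG1-KO D10 replicates 2 and 3. That for Tnf ended in those cases and without C57BL/6 D10 replicate 2, and that for H2-Ab1 without RAG1-KO D10 replicate 2. Over all 18 alternatives, the call for Tnf fell below the threshold in 12. Of 29 calls named for this comparison, 14 stayed past the threshold whichever mouse was left out, among them Iigp1, Igtp, Lgals3, Plaat3, Lst1, Nfkbiz, Nfkbia, Ier2 and Egr1.

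At D4 the genotypes differed in 13 genes of microglia-like cells (9 higher and 4 lower in RAG1-KO; n = 3 and 2), and none met the naming rule. Those given here were chosen after their values were seen. Neutrophil genes were higher in RAG1-KO mice: Lcn2 rose by 2.62 ± 0.30, Retnlg by 2.19 ± 0.36 and Ngp by 1.76 ± 0.29 (edgeR adjusted p = 0.000774, 0.0218 and 0.0209), from 1.23 to 7.56 CPM for Lcn2. The mitochondrially encoded mt-Nd3 was higher too, by 0.90 ± 0.14 (adjusted p = 0.0103), the 1 gene called of 13 such genes, of which 8 rose when adjusted over the list alone (camera adjusted p = 1.51e-10, and adjusted p = 0.266 with an estimated correlation). Of 6 neutrophil transcripts listed as coming from other cells, 3 rose over all genes and 6 when adjusted over the list alone (camera adjusted p = 8.59e-17, and 0.00267 with an estimated correlation). The lymphocyte transcripts Igkc, Cd3d and Trbc2 changed by −5.72 ± 0.71, −4.48 ± 0.77 and −2.68 ± 0.49. MHC class II was not called at D4: none of 10 genes fell, although the set was lower with camera (adjusted p = 0.034, and adjusted p = 0.529 with an estimated correlation), with Cd74 at −1.41 ± 0.59 (edgeR adjusted p = 0.634). None of 28 interferon-gamma induced genes was called over all genes and 3 fell when adjusted over the list alone (camera adjusted p = 2.23e-05, and adjusted p = 0.272 with an estimated correlation). The count fell to 3, 5 and 8 without C57BL/6 D4 replicates 1, 2 and 3, and to 2 and 0 without RAG1-KO D4 replicates 1 and 3, with the remaining RAG1-KO mouse taken to vary like the other groups; none of the 7 calls named stayed in every such fit.

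The genotype difference in microglia-like cells changed between D4 and D10 for 39 genes (16 higher and 23 lower at D10; 11 mice). Ifrd1 and Ets2 and the immediate early list's Ier2 and Nfkbia changed by 2.07 ± 0.33, 1.46 ± 0.22, 1.5 ± 0.26 and 1.40 ± 0.22 on the log2 scale (edgeR adjusted p = 0.0295, 0.00526, 0.0182 and 0.00526). Plaat3 and Ly6c2 changed by −1.59 ± 0.21 and −1.59 ± 0.24 (adjusted p = 0.000941 and 0.00433). Lars2 and AY036118 changed by −1.65 ± 0.17 and −1.38 ± 0.14 (each adjusted p = 6.09e-05). Of 30 immediate early genes, 3 were called and 10 when adjusted over the list alone (camera adjusted p = 2.83e-13, and adjusted p = 0.0854 with an estimated correlation). None of the 10 MHC class II genes was called over all genes and 7 were lower when adjusted over the list alone (camera adjusted p = 1.18e-09, and adjusted p = 0.0854 with an estimated correlation). Mitochondrially encoded transcripts were lower for 7 of 13 genes and 9 adjusted over the list alone (camera adjusted p = 8.58e-17, and adjusted p = 0.0854 with an estimated correlation). The count was 17 and 19 without C57BL/6 D10 replicates 1 and 3, 16 and 17 without C57BL/6 D4 replicates 1 and 2, 110 without RAG1-KO D10 replicate 1 and 7 without RAG1-KO D4 replicate 3. Of the calls named here, Lars2 and AY036118 stayed whichever mouse was left out, and Ets2, Ier2, Nfkbia, Plaat3 and Ly6c2 ended without RAG1-KO D4 replicate 3. No technical explanation for Lars2 and AY036118 was tested. Since capture and group cannot be separated, leaving out mice does not tell these calls from a capture difference. The call for Ifrd1 ended without any 1 of the C57BL/6 D10 mice, C57BL/6 D4 replicates 1 and 2 and RAG1-KO D10 replicates 2 and 3.

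From D4 to D10, microglia-like cells changed broadly in both genotypes. The clusters within the class changed share, cluster 1 from 43.9 to 9.2% and cluster 6 from 3.3 to 32.3% of its pooled cells in C57BL/6, and from 35.9 to 4.9% and from 3.3 to 22.3% in RAG1-KO, which was not tested. In C57BL/6 mice (n = 3 and 3), 2753 of 11627 genes rose and 2320 fell, and in RAG1-KO mice (n = 2 and 3) 2792 rose and 2280 fell. Of the risers 2147 were shared, where independent changes would share 661.1, and of the fallers 1472 were shared against 454.9. The largest rises in C57BL/6 were the fatty acid receptor Cd36 (4.94 ± 0.60), H2-Eb1 (4.29 ± 0.60), the complement genes C4b (4.14 ± 0.47) and Cfb (4.06 ± 0.54), H2-Aa (4.08 ± 0.58), Ms4a7 (3.88 ± 0.60) and Spp1 (3.81 ± 0.88), each with edgeR adjusted p between 0.000288 and 0.0106. Transcripts abundant in macrophages rose in the class as well, with summed Arg1 and Pf4 at 3.7, 2.3 and 2.8 CPM in the C57BL/6 D4 and 84.4, 26.8 and 38.6 CPM in the C57BL/6 D10 replicates. Spp1, H2-Eb1 and Lgals3 also rose in T-like cells, by 4.59, 4.18 and 1.71 on the log2 scale. In RAG1-KO they were Fn1 (5.18 ± 1.00), Spp1 (4.68 ± 1.09), Cd36 (4.20 ± 0.79), Lilr4b (4.17 ± 0.34) and C4b (3.99 ± 0.60). Spp1, a secreted phosphoprotein of activated macrophages, went from 61.3 ± 30.5 to 847 ± 276 CPM in C57BL/6 and from 63.5 ± 14.4 to 1660 ± 1599 CPM in RAG1-KO mice. Damage-associated microglial genes, including Lgals3 and Cd52, rose for 20 of 27 in C57BL/6 (22 adjusted over the list alone) and 19 of 27 in RAG1-KO (23). Their camera adjusted p was 7.85e-09 and 1.23e-08, and adjusted p = 0.132 and 0.0852 with an estimated correlation.

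Genes of proliferation, respiration and antiviral defence rose with them. Of 30 proliferation genes, 29 rose in C57BL/6 (30 adjusted over the list alone) and 30 in RAG1-KO, including Mcm2 (2.00 ± 0.23 and 2.30 ± 0.25) and Pcna (1.21 ± 0.12 and 1.41 ± 0.13). All 33 oxidative phosphorylation genes rose in each genotype. Of 13 mitochondrially encoded transcripts 12 rose in C57BL/6 and 13 in RAG1-KO (as many adjusted over the list alone), mt-Co3 by 2.14 ± 0.12 in C57BL/6 (camera adjusted p = 2.16e-12 and 7.22e-07, and adjusted p = 0.132 and 0.203 with an estimated correlation). Of 35 type I interferon induced genes, 34 rose in C57BL/6 and 33 in RAG1-KO (34 in each adjusted over the list alone), with Oas2 at 2.90 ± 0.26 and 3.00 ± 0.30. Of 28 interferon-gamma induced genes, 22 and 19 rose (25 and 22 adjusted over the list alone), and of 19 MHC class I genes 18 and 17, with B2m going from 1767 to 5363 CPM in C57BL/6. MHC class II genes rose for 7 of 10 in C57BL/6 (7 adjusted over the list alone; camera adjusted p = 3.63e-05, and adjusted p = 0.145 with an estimated correlation), and in RAG1-KO none rose and 1 fell (0 adjusted over the list alone; camera adjusted p = 0.379). Camera called the lists of proliferation, oxidative phosphorylation, type I interferon, interferon-gamma and MHC class I genes in both genotypes, at adjusted p from 0.132 to 0.203 with an estimated correlation. No mouse left out moved the C57BL/6 count by more than 1.5 times, and without RAG1-KO D4 replicate 3 the RAG1-KO count of 5072 was 2689.

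Homeostatic microglial genes, which mark microglia of the undisturbed brain, fell over the same interval, for 21 of 28 in C57BL/6 (22 adjusted over the list alone) and 23 of 28 in RAG1-KO (23), where 1 rose. In C57BL/6, Mef2c fell by 0.72 ± 0.10 and Rhob by 1.04 ± 0.13 on the log2 scale. Camera gave an adjusted p of 8.29e-10 and 8.39e-10, and adjusted p = 0.132 and 0.187 with an estimated correlation. The largest falls in C57BL/6 were Dbp (−3.02 ± 0.20), Per3 (−2.77 ± 0.21), Ttr (−2.59 ± 0.17), Dnajb1 (−2.35 ± 0.30) and Tef (−2.24 ± 0.21), and in RAG1-KO Dbp (−3.81 ± 0.17), Ttr (−3.46 ± 0.14), Hspa1b (−3.15 ± 0.92) and Hspa1a (−2.78 ± 0.87). Dbp, Per3 and Tef are output genes of the circadian clock, and Dbp went from 41.0 ± 5.54 to 4.96 ± 0.90 CPM in C57BL/6. Immediate early genes fell for 21 of 30 (22 adjusted over the list alone) and rose for 2 in C57BL/6, with Jun at −1.84 ± 0.15 and Fos at −1.66 ± 0.17 (camera adjusted p = 2.08e-09, and adjusted p = 0.132 with an estimated correlation). In RAG1-KO, 10 fell and 6 rose (camera adjusted p = 0.0718). In C57BL/6 all 23 calls named stayed whichever mouse was left out. In RAG1-KO 9 of 14 did, while Hspa1a and Hspa1b ended without RAG1-KO D10 replicates 2 or 3 or either D4 mouse, and Cd36, Fn1 and Spp1 without D4 replicate 3.

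In monocyte/macrophage-like cells at D10, S100a8 and Vcan were higher and Folr2 lower in RAG1-KO than in C57BL/6 mice (n = 3 and 3), calls that each ended without C57BL/6 D10 replicate 1. The genotypes differed in the clusters of this class, with 43.8% against 13.1% of its pooled cells in cluster 2 and 18.1% against 31.2% in cluster 4 (C57BL/6 against RAG1-KO), which was not tested. S100a8, a calcium-binding protein of monocytes and neutrophils, rose by 2.90 ± 0.54 (edgeR adjusted p = 0.034; 22.7 ± 4.20 against 182 ± 67.8 CPM). It is also 1 of 2 genes called (7 higher and 1 lower adjusted over the list alone) among 10 neutrophil transcripts listed as coming from other cells. The other was Retnlg, at 3.40 ± 0.35. Camera gave this list an adjusted p of 0.000628, and adjusted p = 0.15 with an estimated correlation. The origin of these transcripts was not tested, and S100a8 may be made by the monocytes themselves. E2f2, Fkbp5, Cirbp, Cd33 and Hopx rose by 1.49 ± 0.23, 1.49 ± 0.30, 1.45 ± 0.30, 1.44 ± 0.26 and 1.40 ± 0.29 (adjusted p = 0.00413, 0.029, 0.0339, 0.0148 and 0.0325). Vcan, which is abundant in monocytes from blood, rose by 1.24 ± 0.22 (adjusted p = 0.0138), and Nr4a2, Klf9, Trem1 and Arhgef37 by 1.20 to 1.12. Folr2, a marker of tissue macrophages, fell by 2.65 ± 0.49 on the log2 scale (adjusted p = 0.0301; 64.9 ± 23.2 against 11.5 ± 1.96 CPM), and Anpep, Ifi27 and Tpm1 by 1.65 ± 0.36, 1.22 ± 0.23 and 1.21 ± 0.13.

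Macrophage programmes in that comparison gave mixed results. Of 24 alternatively activated or suppressive macrophage genes, Folr2, Ccl24 and Pdcd1lg2 fell and Trem1 rose (3 lower and 4 higher adjusted over the list alone; camera adjusted p = 0.155), with Ccl24 at −2.17 ± 0.37. Of 29 inflammatory cytokines and chemokines, Il6 and Ccl3 rose by 1.80 ± 0.27 and 0.75 ± 0.15 and 1 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.859). Glycolysis and hypoxia genes fell for 4 of 24, Pfkl, Pdk1, Higd1a and Aldoc, and for 6 when adjusted over the list alone (camera adjusted p = 3.12e-07, and adjusted p = 0.368 with an estimated correlation). Proliferation genes were lower as a set, with 1 of 20 called and 5 adjusted over the list alone (camera adjusted p = 4.37e-06, and adjusted p = 0.113 with an estimated correlation). None of 9 MHC class II and none of 29 interferon-gamma induced genes was called, although both sets were lower with camera (adjusted p = 7.58e-05 and 0.00955, and adjusted p = 0.368 and 0.742 with an estimated correlation). Lymphocyte transcripts listed as coming from other cells fell for 6 of 10 (7 adjusted over the list alone), with Cd3d at −5.73 ± 0.39 (camera adjusted p = 6.17e-09, and adjusted p = 0.113 with an estimated correlation). Altogether 235 of 9911 genes passed, 122 higher and 113 lower in RAG1-KO mice. The count was 11 without C57BL/6 D10 replicate 1, 21 without replicate 3, 540 without RAG1-KO D10 replicate 1, 55 without replicate 2 and 48 without replicate 3. Of 25 calls named, Tpm1, Retnlg and Cd3d stayed whichever mouse was left out, and 22 ended without C57BL/6 D10 replicate 1. The count was 0 with 100 cells per mouse. It was 29 without the clusters that scored highest for border-associated macrophages, a resident population of the meninges and vessels. Among these clusters was cluster 2, led by Arg1, Pf4, Ccl8, Ms4a7 and Ecm1. It had 4 markers of that population among its 10 top genes, short of the 5 the name needed, so it need not be that population.

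At D4 the genotypes differed in 3 genes of monocyte/macrophage-like cells, all higher in RAG1-KO mice (n = 3 and 2). Cluster 7 held 28.6% of the pooled cells in C57BL/6 and 6.6% in RAG1-KO, and cluster 19 held 11.3% and 28.0%, which was not tested. Retnlg rose by 3.47 ± 0.47, Atp11a by 1.87 ± 0.27 and Gda by 1.39 ± 0.20 (edgeR adjusted p = 0.0169 for each), and Gda went from 203 ± 35.6 CPM in C57BL/6 to 535 ± 96.3 CPM in RAG1-KO. Gda met the naming rule, and the others were added after their values were seen. Of 10 neutrophil transcripts listed as coming from other cells, Retnlg among them, 1 rose over all genes and 6 when adjusted over the list alone (camera adjusted p = 6.7e-12, and 0.0222 with an estimated correlation). Their origin was not tested here either. The genotype difference changed between D4 and D10 for 3 genes, all mitochondrially encoded: mt-Nd3, mt-Nd1 and mt-Co3 (−1.69 ± 0.22, −1.43 ± 0.22 and −1.42 ± 0.21). None of these 6 calls stayed in every fit that left out a mouse. At D4 the count was 0 without C57BL/6 D4 replicate 1 or RAG1-KO D4 replicate 1, 1 without C57BL/6 D4 replicate 3 and 23 without RAG1-KO D4 replicate 3. For the change between D4 and D10 it was 0 without any 1 of the 3 C57BL/6 D4 mice, RAG1-KO D10 replicate 2 or RAG1-KO D4 replicate 1, 6 and 5 without C57BL/6 D10 replicates 2 and 3, and 50 without RAG1-KO D4 replicate 3.

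From D4 to D10 in C57BL/6 mice, some genes of glycolysis, hypoxia and suppressive macrophages rose in monocyte/macrophage-like cells, and genes shared with microglia fell (n = 3 and 3). The clusters within the class changed share, cluster 2 from 3.8 to 43.8% and cluster 7 from 28.6 to 14.0% of its pooled cells, which was not tested. The chemokine Cxcl3 rose by 6.46 ± 0.78, Ocstamp by 3.44 ± 0.46, Sdc1 by 3.01 ± 0.65 and the protease Adam8 by 2.57 ± 0.45 (edgeR adjusted p = 0.00217, 0.00162, 0.023 and 0.0106). Of 24 glycolysis and hypoxia genes, 9 rose over all genes and 16 when adjusted over the list alone (camera adjusted p = 2.53e-11, and adjusted p = 0.246 with an estimated correlation). The glucose transporter Slc2a1 rose by 1.64 ± 0.34 and Ndrg1 by 1.70 ± 0.31. Il4ra, Msr1 and Il10 were among 6 of 24 alternatively activated or suppressive macrophage genes that rose, at 1.40 ± 0.21, 1.30 ± 0.24 and 2.23 ± 0.46, while 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 6.62e-05, and adjusted p = 0.138 with an estimated correlation). Mitochondrially encoded transcripts rose for 8 of 13 genes (11 adjusted over the list alone), with mt-Co3 at 1.20 ± 0.14 (camera adjusted p = 1.84e-10, and adjusted p = 0.246 with an estimated correlation). Of 26 homeostatic microglial genes 17 fell (18 adjusted over the list alone; camera adjusted p = 3.2e-13, and adjusted p = 0.138 with an estimated correlation), over the interval in which the microglia-like share went from 72.9 to 19.0%. In T-like cells 6 of 17 such genes fell as well and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 9.89e-05, and adjusted p = 0.449 with an estimated correlation), P2ry12 by 2.40 ± 0.41 on the log2 scale. Rhob, Tgfbr1 and Jun were among them, at −1.26 ± 0.24, −1.05 ± 0.24 and −0.96 ± 0.19. Jun is also named above as an immediate early gene, so not all of these need be transcripts of microglia. The largest falls in monocyte/macrophage-like cells were Gpr34, a microglial receptor, by 3.92 ± 0.46, Ttr, a transcript of the choroid plexus, by 3.65 ± 0.66 and Hpgd by 3.53 ± 0.32 on the log2 scale. Cxcl3, Ocstamp, Ndrg1, Il4ra, Msr1, mt-Co3, Gpr34 and Hpgd stayed past the threshold whichever mouse was left out, and Sdc1, Adam8, Slc2a1, Il10 and Ttr ended without C57BL/6 D10 replicate 1. In all, 470 genes rose and 478 fell, 948 together. The count was 196 without C57BL/6 D10 replicate 1, 266 without D10 replicate 3, 353 without D4 replicate 1 and 560 without D4 replicate 3. It was 426 without the clusters that scored highest for border-associated macrophages, among them cluster 2, led by Arg1 and Pf4.

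In RAG1-KO mice, 54 genes of these cells rose and 38 fell from D4 to D10 (n = 2 and 3). Cluster 19 went from 28.0 to 6.3% of the pooled cells, cluster 4 from 14.8 to 31.2% and cluster 2 from 4.1 to 13.1%, which was not tested. Ocstamp, Cd276 and Myo1e rose by 3.02 ± 0.54, 2.61 ± 0.43 and 2.58 ± 0.51 (edgeR adjusted p = 0.0216, 0.0126 and 0.0289). The chemokine Cxcl2 rose by 1.38 ± 0.20 (adjusted p = 0.00734), the only gene called of 29 inflammatory cytokines and chemokines (4 adjusted over the list alone; camera adjusted p = 6.38e-05, and adjusted p = 0.244 with an estimated correlation). B2m and H2-Q6 rose by 0.84 ± 0.15 and 1.31 ± 0.23, the 2 MHC class I genes called of 19 (8 adjusted over the list alone; camera adjusted p = 7.83e-08, and adjusted p = 0.421 with an estimated correlation). Hpgd and Cebpd fell by 2.19 ± 0.33 and 1.41 ± 0.22 on the log2 scale. Of 26 homeostatic microglial genes Siglech and Crybb1 fell, and 12 when adjusted over the list alone (camera adjusted p = 1.56e-06, and adjusted p = 0.313 with an estimated correlation). The genotypes shared 38 of the risers, against 2.6 for independent changes, and 23 of the fallers, against 1.8. The count of 92 was 38 and 47 without RAG1-KO D10 replicates 2 and 3, 10 without RAG1-KO D4 replicate 1, which ended 8 of the 10 calls named, and 368 without RAG1-KO D4 replicate 3, and 0 when the RAG1-KO mice were fitted alone.

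Naive and memory genes fell in T-like cells of C57BL/6 brains between D4 and D10, while Lag3, Pdcd1 and Gzmb rose (n = 3 and 3). The clusters within the class changed share, cluster 13 from 51.5 to 15.8%, cluster 16 from 2.6 to 28.0% and cluster 21 from 3.0 to 17.7% of its pooled cells, which was not tested. With stricter cell filters, a T-like cluster was led by Tnfrsf4, Ctla4, Icos and Ikzf2, with the regulatory T-cell gene Foxp3 among its top genes. It had 1, 7 and 5 cells in C57BL/6 D4 and 123, 2 and 261 in C57BL/6 D10 replicates 1 to 3. The changes below can be of the mix of T-like cells or within them, which was not separated. Lef1 and Tcf7, transcription factors of naive and memory T cells, fell by 2.44 ± 0.13 and 2.40 ± 0.12 on the log2 scale (each edgeR adjusted p = 1.53e-07), Tcf7 from 265 ± 29.2 to 51.0 ± 5.05 CPM. Of 14 naive and memory genes 13 fell (13 adjusted over the list alone), Ccr7 and S1pr1 among them (camera adjusted p = 4.6e-13, and adjusted p = 0.115 with an estimated correlation). The inhibitory receptors Lag3 and Pdcd1 rose by 2.47 ± 0.22 and 1.83 ± 0.31 (adjusted p = 1.59e-05 and 0.00466), Lag3 from 15.6 ± 3.21 to 84.2 ± 18.8 CPM, among 5 of 17 checkpoint genes that rose (6 adjusted over the list alone; camera adjusted p = 0.00112, and adjusted p = 0.449 with an estimated correlation). Of 23 effector genes, Gzmb, a protease of killing lymphocytes, rose by 2.24 ± 0.33 from 398 ± 154 to 1876 ± 198 CPM, and Tnf, Cx3cr1 and Fasl fell by 1.14 ± 0.26, 1.90 ± 0.36 and 0.61 ± 0.18 on the log2 scale (1 higher and 3 lower also adjusted over the list alone; camera adjusted p = 0.0375, and adjusted p = 0.449 with an estimated correlation). Proliferation genes rose for 20 of 30 (27 adjusted over the list alone), with Aurkb at 2.29 ± 0.23, and oxidative phosphorylation genes for 30 of 33, or 31 adjusted over the list alone (camera adjusted p = 2.61e-16 and 1.11e-17, and adjusted p = 0.449 and 0.0619 with an estimated correlation). Mitochondrially encoded transcripts rose for 8 of 13 genes and fell for 1 (also adjusted over the list alone), with mt-Co3 at 1.11 ± 0.10. Ribosomal protein genes fell for 17 of 30 (19 adjusted over the list alone), with Rps7 at −0.73 ± 0.08, and immediate early genes for 13 of 28 (14), with Klf2 at −1.92 ± 0.20. Camera gave these 3 lists adjusted p = 0.000595, 6.06e-08 and 9.89e-05, and adjusted p = 0.456, 0.456 and 0.449 with an estimated correlation.

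Genes abundant in macrophages led the rises in T-like cells by size, with Pf4, Spp1, Cxcl2 and Tgfbi at 6.18 ± 1.36, 4.59 ± 0.76, 4.58 ± 0.82 and 4.43 ± 0.75, over the interval in which monocyte/macrophage-like cells took a larger share of each sample. MHC class II genes rose for 4 of 6 (5 adjusted over the list alone), with H2-Eb1 at 4.18 ± 1.06 (camera adjusted p = 0.03, and adjusted p = 0.458 with an estimated correlation). The largest falls were Igfbp4 (−5.02 ± 0.28), Rflnb (−3.52 ± 0.24), Dapl1 (−3.42 ± 0.23) and Cd40lg (−2.76 ± 0.25). Of 7311 genes, 1091 rose and 1095 fell. The total of 2186 was 1416 without C57BL/6 D10 replicate 1 and 1315 without cycling cells. Of 25 calls named, those for Pf4, H2-Eb1, Tnf, Cx3cr1 and Fasl ended without 1 mouse or another.

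NK-like, dendritic-like and neutrophil-like cells showed few genotype differences, averaged over D4 and D10. In NK-like cells (11 mice) 4 of 7466 genes passed; genes of this paragraph outside the naming rule were chosen after their values were seen. Egr1 rose by 1.33 ± 0.18 and S100a9 by 1.20 ± 0.23, while Cd74 fell by 1.12 ± 0.19 and Hist1h1e by 0.69 ± 0.13 on the log2 scale (edgeR adjusted p = 0.000318, 0.0265, 0.00842 and 0.0265). Cd74 in these cells was read above as background from other cells, and the summed class II CPM of NK-like cells was itself 369.5, 413 and 387 in the C57BL/6 D10 and 107, 119 and 122 in the RAG1-KO D10 replicates. In dendritic-like cells (9 mice, of which RAG1-KO D4 replicate 3 alone stands for its group) Smim5 fell by 2.99 ± 0.26 on the log2 scale and S100a9, a neutrophil gene, rose by 1.89 ± 0.22, of 10081 genes (adjusted p = 0.000902 and 0.00405). S100a9 had 73.2 CPM in that mouse and a mean of 15.3 in RAG1-KO D10, 13.1 in C57BL/6 D4 and 6.52 in C57BL/6 D10 mice. Neutrophil transcripts listed as coming from other cells were higher as a set in dendritic-like cells, with 1 of 5 called and 3 adjusted over the list alone (camera adjusted p = 2.56e-08, and 0.0368 with an estimated correlation). In neutrophil-like cells (9 mice) edgeR called 0 of 4223 genes, with 193 at an unadjusted p under 0.05, and DESeq2 called 1. There, 6 of 6 MHC class II genes and 6 of 17 interferon-gamma induced genes fell when adjusted over the list alone (camera adjusted p = 4.03e-08 and 2.04e-05, and adjusted p = 0.333 for each with an estimated correlation). Other lists were lower there too with camera, with 0 genes called adjusted over the list alone: ribosomal protein, mitochondrially encoded, and glycolysis and hypoxia genes (adjusted p = 1.97e-10, 1.37e-06 and 1.44e-08, and adjusted p = 0.347, 0.347 and 0.333 with an estimated correlation). Class II transcripts in NK-like cells, given above, were lower in RAG1-KO mice as well. Egr1 stayed past the threshold whichever mouse was left out, and Smim5 in the 8 fits that could be run, since no fit is possible without RAG1-KO D4 replicate 3; the others did not. The NK count was 2 without C57BL/6 D10 replicates 1 or 3 or C57BL/6 D4 replicates 1 or 2, 14 without RAG1-KO D4 replicate 1 and 1 without replicate 3. The dendritic count was 1 without C57BL/6 D10 replicate 3, 5 without C57BL/6 D4 replicate 2 and 10 without RAG1-KO D10 replicate 1, and it was 99 with no filter on low counts.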

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

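The tests of the interaction and the fits without 1 mouse were planned, and the reading of the tag counts was chosen after they were seen. The genotype difference of 39 genes in microglia-like cells and of 3 genes in monocyte/macrophage-like cells differed between D4 and D10, which a test of the interaction picked out. Without RAG1-KO D4 replicate 3 these counts were 7 and 50. The 3 genes, mt-Nd3, mt-Nd1 and mt-Co3, are all mitochondrially encoded, and mt-Nd3 and mt-Co3 were among the 39 as well, at −1.52 ± 0.19 and −1.42 ± 0.17. No technical explanation for them was tested, and the capture of each group in its own droplet run leaves run and group inseparable.

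The tag CMO308, which no file set of the group has as its own, gave 57341 UMIs in RAG1-KO D4 replicate 1 and 322669 in RAG1-KO D4 replicate 3. It was picked out as a signal in data that no comparison uses. Cells of a mouse with that tag were not analysed here.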

How the results depend on the processing

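Of the alternatives, leaving out cycling cells, stress-led clusters, border-associated or immature neutrophil clusters, or adding the border-associated cluster, was chosen after the data were seen; the others were planned. Among the 168 gene calls named in the text, 0 changed direction in 3029 refits, 68 stayed past the threshold in all of them and 100 fell below it in at least 1. The genotype differences in T-like, B-like and neutrophil-like shares and the changes from D4 to D10 in microglia-like, monocyte/macrophage-like and dendritic-like shares kept their direction and side of the threshold in every alternative run. Left-out mice moved the genotype difference between −15.9 and −8.26 points for monocyte/macrophage-like, −3.35 and −2.24 for dendritic-like, and −0.758 and 2.34 for NK-like cells. By unadjusted p, the first passed without C57BL/6 D10 replicate 2 and the dendritic-like difference passed in 3 of 11 such fits. The NK-like difference changed sign, though never past the threshold, at −0.727 and −0.366 without C57BL/6 D10 replicates 1 and 3, −0.141 without C57BL/6 D4 replicate 1, −0.758 without RAG1-KO D10 replicate 1 and −0.593 without RAG1-KO D4 replicate 1. With the other denominator the microglia-like difference was 17.1 points and passed by unadjusted p, and the dendritic-like difference was −0.667 points and did not; the shares of T-like and B-like cells enter that denominator. Estimated correlations left 7 of 165 gene list calls, as they widen the null distribution of lists whose genes move together.

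Numbers of called genes moved by more than 1.5 times as follows, and except where stated the cause was not tested. With DESeq2's Wald test the count was 26 for microglia-like cells by genotype at D4, and for monocyte/macrophage-like cells 44 at D4, 123 at D10, 23 for the interaction and 199 from D4 to D10 in RAG1-KO. It was 1449 for T-like, 16 for dendritic-like and 1 for neutrophil-like cells. With no filter on low counts, microglia-like cells had 168, 813 and 284 (D4, D10 and interaction), monocyte/macrophage-like cells 27, 437, 39 and 302 (D4, D10, interaction and RAG1-KO over time), and dendritic-like, NK-like and neutrophil-like cells 99, 30 and 4. With stricter cell filters, microglia-like cells had 145 at D10 and 24 for the interaction, monocyte/macrophage-like cells 5 at D4, 9 for the interaction and 416 over time in RAG1-KO, and dendritic-like cells 1. With at most 100 cells per mouse, which removes depth by construction, microglia-like cells had 3, 82 and 12 by genotype at D4, D10 and for the interaction, and 2083 and 1399 over time in C57BL/6 and RAG1-KO. Monocyte/macrophage-like cells then had 0, 0 and 0, and 174 and 9 over time, and T-like cells 1215. Fewer cells lower such counts by construction, so these values do not show how far depth limits the main counts.

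Counting the identical file set as a mouse, which adds no animal, gave 30 and 84 for microglia-like cells at D4 and for the interaction, and 38, 22 and 827 for monocyte/macrophage-like cells at D4, for the interaction and over time in RAG1-KO. With only the groups compared in the fit, microglia-like cells had 114 at D4 and 127 at D10, and monocyte/macrophage-like cells 0 at D4, 399 at D10 and 0 over time in RAG1-KO. Without clusters scored as border-associated, monocyte/macrophage-like cells had 29 by genotype at D10 and 426 over time in C57BL/6, and with the border-associated cluster 5 for the interaction and 588 over time in RAG1-KO. Without the cluster led by stress genes the microglia-like interaction had 25. Keeping doublets gave 1 in neutrophil-like cells, at least 50 cells per mouse 9 in NK-like cells, and leaving out cycling cells 2 in NK-like and 1315 in T-like cells.

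Leaving out each mouse in turn gave 0 to 8, 75 to 792 and 7 to 110 genes in microglia-like cells (D4, D10 and interaction) and 2689 to 5223 over time in RAG1-KO. In monocyte/macrophage-like cells it gave 0 to 23, 11 to 540 and 0 to 50, and over time 196 to 994 in C57BL/6 and 10 to 368 in RAG1-KO. It gave 1416 to 2222 in T-like, 1 to 14 in NK-like and 1 to 10 in dendritic-like cells. DESeq2's size factors and resolution 2 left every count within 1.5 times. T-like cells over time have no value with the identical file set or with only the compared groups, since no RAG1-KO mouse enters that fit. No paired analysis was possible because no mouse was sampled at both times.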

Other observations

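The tests of explanations and the comparisons of other groupings in this part were chosen after the results they concern were seen. Some 254 cells resembled border-associated macrophages, which live in the meninges and around vessels. Their mean share was 1.72% ± 0.742 (SD) in C57BL/6 and 2.03% ± 0.368 in RAG1-KO brains at D4, and 0.144% ± 0.15 and 0.347% ± 0.317 at D10. Endothelial-like cells followed, with means of 1.45% and 1.61% at D4 and 0.024% and 0.026% at D10. Innate lymphoid-like cells (55 in all) averaged 0.281%, 0.41%, 0.046% and 0.2% in C57BL/6 D4, RAG1-KO D4, C57BL/6 D10 and RAG1-KO D10 brains. Another 35 tumour- or epithelial-like cells, with a median of 90523 UMIs, passed the CD45 selection, and 157 cells remained unnamed.

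Microglia-like cells spread over 6 main clusters whose shares differed between groups. The cluster numbered 3 held 35.2% of them in RAG1-KO brains at D10 and 11.5% in C57BL/6 brains at D10, against 10.4% and 13.7% at D4. From D4 to D10 cluster 6 went from 3.3 to 32.3% and cluster 1 from 43.9 to 9.2% in C57BL/6, and to 22.3 and 4.9% in RAG1-KO brains at D10. Among monocyte/macrophage-like cells, cluster 2 held 43.8% in C57BL/6 and 13.1% in RAG1-KO brains at D10, against 3.8% and 4.1% at D4, and cluster 4 held 18.1% and 31.2% at D10. These shares were not tested.

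MHC class II transcripts were lower in RAG1-KO than in C57BL/6 microglia-like cells at D10. The class II CPM of microglia-like cells was 7.10, 2.69 and 8.33 times that of NK-like cells in the C57BL/6 D10 replicates. This argues against free RNA in the droplets as the whole source of the summed level. The ratio was 3.86, 1.85 and 2.16 in the C57BL/6 D4 and 2.56, 1.30 and 1.14 in the RAG1-KO D10 replicates. It was 1.19 and 2.05 in RAG1-KO D4 replicates 1 and 3. C57BL/6 D10 replicate 2 thus lay within the range of mice low in class II, and replicates 1 and 3 above it. The summed level rests in large part on few cells, as the top twentieth held 51.0, 34.5 and 44.1% of its UMIs in the C57BL/6 D10 replicates. In the median cell the ratio was 1.32 in the lowest mouse, replicate 2 with 24 NK-like cells, too close to 1 to decide. There free RNA cannot be told apart from transcripts of the cells themselves. Macrophages or dendritic cells mixed into the class, scaled by Arg1 and Pf4 and by dendritic markers, would bring less than was seen. The median ratio of observed to expected was 3.29 (3.29, 1.68 and 6.30 per mouse). In the RAG1-KO D10 replicates it was 0.66, 0.36 and 0.53, so the expected level is itself inexact. Macrophages low in Arg1 and Pf4 would go uncounted, so mixing is not excluded. Within clusters, the lower of C57BL/6 replicates 1 and 3 was set against the highest RAG1-KO mouse with 20 cells there. The ratio was 12.09, 10.49 and 7.49 in clusters 6, 15 and 18, so a shift between clusters is not the whole source. It was 3.19, 2.67 and 2.69 in clusters 0, 1 and 3. NK-like cells, the background, had 369.5 and 387 CPM in those C57BL/6 replicates and 107, 119 and 122 in the RAG1-KO D10 replicates. Free RNA may therefore give the gap in clusters 0, 1 and 3. Replicate 2 had too few cells in each cluster, and its 1110 CPM over the class stood above the 316 CPM that was highest for a RAG1-KO mouse in any of these clusters. Capture differences cannot be told apart from genotype, as 0 barcodes were shared within groups, and the absence of T cells, which make interferon gamma, may underlie it and was not tested.

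Output genes of the circadian clock were lower at D10 than at D4 in microglia-like cells of both genotypes, for 7 of 9 in C57BL/6 and 8 of 9 in RAG1-KO mice. Within clusters 0, 1 and 3, the ones run of the 6, the lowest D4 mouse had at least 2.31 times the summed Dbp, Per3, Tef and Nr1d2 of the highest D10 mouse with 20 cells there, which argues against a shift between clusters as the whole source. C57BL/6 D10 replicate 2 had too few cells to enter, as had RAG1-KO D10 replicate 3 in cluster 1. Harvest at another time of day may explain it, yet it cannot be told apart from an effect of the tumour. Arntl, which peaks when Dbp is lowest, changed by 0.15 ± 0.33 in C57BL/6 and 0.64 ± 0.30 in RAG1-KO. Neither change was called, though Arntl passed as a rise in 2 of 16 alternatives in RAG1-KO and in 0 of 17 in C57BL/6. Of 4 genes high when Dbp is low, Arntl among them, 1 rose and 2 fell in C57BL/6 (median −0.08 on the log2 scale), and in RAG1-KO 1 rose (median 0.21). Of 6 output genes measured in monocyte/macrophage-like cells 3 fell in C57BL/6 (median −0.90), and none was called in RAG1-KO (median −1.10). The hour of harvest is not given in the sources used here.

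The neutrophil-like share was higher in RAG1-KO mice, and 115 of the 194 neutrophil-like cells of RAG1-KO D4 replicate 3 sat in the cluster led by Ngp, Camp and Ltf, genes of marrow neutrophils. Without that cluster the difference was 2.05 points (exact two-sided permutation p = 0.02), which argues against the cells of that cluster as its whole source. Other neutrophils of marrow would stay in the share, so marrow in some samples is not excluded. RAG1-KO D4 replicate 3 also held all 19 B-like cells of RAG1-KO mice, which carried genes of B-cell precursors. Marrow in some samples, a difference between genotypes and one between captures stay open, all untested.

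Other groupings of the mice were compared with the real one by the number of genes called. The 10 splits of 3 against 3 are too few to reach a share under 0.05. In these the real split ranked 1 of 10 each time: 289 against at most 108 for microglia-like cells at D10 by genotype, 235 against 36 for monocyte/macrophage-like cells, and from D4 to D10 in C57BL/6 mice 5073, 948 and 2186 in microglia-like, monocyte/macrophage-like and T-like cells against 0. For NK-like cells 8 of 100 splits called as many as 4 genes (highest other 12), for dendritic-like cells 6 of 40 called as many as 2 (highest other 85). Chance cannot be excluded for these 2 classes. For neutrophil-like cells the real count was 0, so all 60 of 60 splits reach it by construction and nothing is decided (highest other 135). For NK-like and dendritic-like cells the median of the other splits was 0, and the highest called several times the real count, which points to a structure of the samples that was not tested.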
